A study of Homo sapiens with 12 samples.

How the data were processed

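The series measured RNA of A549 monolayers on 12 Affymetrix PrimeView arrays, in 4 groups of 3: untreated, heat shocked for 2 h, wounded for 4 h, and heat shocked and then wounded. Each array received 100 ng of total RNA, isolated with Trizol and labelled with the 3' IVT Express kit, per the labels' protocols. The deposited values are log2 probe set levels, 1 column per array, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, sets all arrays to 1 distribution and sums the probes of a probe set. The program's version and any later filter are not given in the sources used here. The log2 scale was read from the range of the values. Scanner files were not used here, so background correction could not be repeated and no detection p was at hand, and RMA can leave dim probe sets on a floor where differences are compressed.

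The table held 49293 probe sets, and 1 with a missing value was left out. The platform annotation gave 1 gene symbol to 44988 probe sets and several to 1832, and 2473 were not listed. Of those with 1 symbol, 44961 matched a gene of the RefSeq gene table of assembly GRCh38.p14 by identifier, and 0 symbols needed updating. That table was used for names only. Probe sets with several symbols or none listed were kept out of the tests by gene. Each gene was read through the probe set with the highest mean over the 12 arrays, which gave 18132 genes, 11734 of them with more than 1 probe set. Among called genes, another probe set passed in the opposite direction for 12 after heat shock, 0 after wounding and 42 after both against control, and for 22, 0 and 0 in the comparisons with wounding, with heat shock and for the interaction. Some genes of the lists, such as HSPA1A, were not analysed here.

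Groups were taken from the labels. A linear model with 1 mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings, 8 residual degrees of freedom), without a replicate block. The comparisons were each treated group against control, both treatments against each single one, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, with no fold threshold. Every adjusted p of a gene in the text comes from limma. Intervals after ± are SD for levels and SE for differences. The tests, the 33 gene lists, the rule for named genes and the alternatives were chosen before the data were examined.

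The rule named, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among those called with no overlap between the values of the groups, for the interaction the 5 smallest p where fewer than 5 genes passed, up to 4 called members of each list by size of change (up to 2 with the smallest p where none passed), and a fixed set that included FGF1, FGF2, the FGF receptors, HSF1, heat shock genes, FOS, EGR1, MMP1, PLAU, GAPDH and ACTB. The text gives part of these. HSPA2 was named after its value was seen.

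Gene lists were tested with camera (preset correlation of 0.01 between genes, and again with the correlation estimated for each list), adjusted over the 33 lists within a comparison. Lists held heat shock proteins and HSF1 targets, heat shock factors, TRiC subunits, endoplasmic reticulum stress, immediate early genes, fibroblast growth factors, FGF receptors and feedback, EGF receptor family, TGF-beta signalling, extracellular matrix, epithelial mesenchymal transition, matrix proteases, cytokines, integrins and migration, YAP and SRF targets, cell cycle, p53 targets, apoptosis, NRF2, metallothioneins, proteasome, cholesterol synthesis, hypoxia, interferon-induced genes, histones, ribosomal proteins, oxidative phosphorylation, markers of alveolar type II and type I cells, fibroblasts, endothelium and leukocytes, and housekeeping genes. Some genes stand in more than 1 list. With the preset correlation 14, 10, 15, 10, 9 and 2 lists passed in the 6 comparisons, and 3, 3, 5, 0, 3 and 0 of them held with an estimated correlation.

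The tests were checked on simulated data with the means and spreads of the 18132 real genes. For heat shock against control, 42 of 50 genes changed by 0.5 on the log2 scale, 49 of 50 changed by 1 and 50 of 50 changed by 2 were called, with 2.6% of calls false. For the interaction, all 50 genes changed by 1 and all 50 changed by 1.6 were called, with 5.7% of calls false. The simulated data gave 283 interaction calls and the real arrays 1. The adjusted threshold was therefore looser in the simulation, and these shares do not give the power of the interaction test on the real arrays. In the heat shock comparison camera called 5 of 5 shifted lists and 0 of 20 unshifted ones. The simulated genes were drawn independently, so this check does not cover false calls from correlation between the genes of a list.

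Alternatives were quantile normalization again, median centring, cyclic loess, leaving out the lowest 30% or 50% of genes by mean, the mean of all probe sets of a gene, all probe sets tested separately, eBayes with trend and robust prior, array weights, a replicate or set block, averaging the S2 arrays, fits with the compared groups alone, added fold thresholds, an adjusted p under 0.01, and leaving out each array in turn. A fit within set S2, list counts without heat shock and wounded replicate 2 alone and list tests without each array were added after the data were seen. Figures were drawn with matplotlib 3.10.9.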

Results

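Gene expression was measured in monolayers of A549, a human lung adenocarcinoma cell line with features of alveolar type II epithelium. The cells were untreated, heat shocked for 2 h, wounded for 4 h, or heat shocked and then wounded. Each of the 4 groups had 3 arrays, which gave 12 Affymetrix PrimeView arrays in all. The series asked whether the heat shock response changes the wound response of lung epithelium, and its title names fibroblast growth factor 1 (FGF1). The labels do not say when the monolayers that were only heat shocked were collected, or whether the arrays of a group came from separate cultures. The p-values set differences against the spread between these samples. That spread may be technical and may leave out variation between cultures. The design gives a 2 h heat shock alone, a 4 h wounding alone and both, and therefore 5 comparisons of groups and 1 interaction.

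The table held 49293 probe sets, and 18132 genes were tested, each through 1 probe set. The median log2 level lay between 5.3 and 5.32 on every array, and replicate arrays correlated at 0.994 to 0.9982. The first principal component held 44.2% of the variance. It ordered the arrays as control (-21.6 to -19.8), wounded (-12 to -7.4), heat shocked (6 to 9.9) and both (17 to 29). Both treatments thus moved the arrays the same way along it, heat shock further than wounding. The second component held 16% and separated monolayers that were wounded alone from those heat shocked alone. Replicate 2 of the heat shocked and wounded group stood apart: its interquartile range was 3.98, against 4.13 to 4.24 for the other arrays, and its correlations within the group were 0.994 and 0.9951.

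Heat shock alone raised chaperone genes. HSPA6, a strictly stress-inducible HSP70 gene, rose from 4.30 ± 0.19 to 10.09 ± 0.55 (SD, n = 3), by 5.79 ± 0.26 on the log2 scale (SE; 55.3-fold; limma adjusted p = 6.03e-08). SERPINH1, the collagen chaperone HSP47, rose 8.59-fold, HSPA4L 8.51-fold, the small heat shock protein gene HSPB8 6.93-fold and the co-chaperone gene BAG3 6.68-fold. HSPA1B rose 4.99-fold, DNAJB1, an HSP40 gene, 3.95-fold, HSPB1 3.39-fold and HSP90AA1 1.46-fold. The constitutive gene HSPA8 differed by 0.09 ± 0.06 (adjusted p = 0.434) and HSF1, the main heat shock transcription factor, by 0.15 ± 0.08 (adjusted p = 0.266), neither past the threshold. Background was not measured here, and 23 leukocyte and endothelial marker genes had an upper quartile of 4.92 in control, so folds that start or end under that level, such as that of HSPA6, are approximate. HSPA6 and HSPA1B have near-identical paralogs, so their probe sets may read more than 1 gene. Of the 36 measured heat shock proteins and HSF1 targets, 29 rose, 1 fell and 6 did not pass, and 33 rose and 1 fell when adjusted over the list alone. The member that fell was HSPA2, by 0.92 on the log2 scale, named after its value was seen. The list stood above other genes (camera adjusted p = 3.63e-45, and adjusted p = 0.0235 with an estimated correlation). Of the 8 subunits of the cytosolic chaperonin TRiC, 5 rose, also 5 adjusted over the list alone, CCT6A by 0.57 and TCP1 by 0.40 (adjusted p = 3.86e-06, and 0.0235 with an estimated correlation). Without the array that stood apart, an alternative added after the data were seen, the estimated correlation gave this list an adjusted p of 0.0715. None of the 5 measured heat shock factors and their partners passed, and none did adjusted over the list alone.

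Strong changes after heat shock were not limited to chaperone genes. PGF, which encodes placental growth factor, rose 10.4-fold, the chemokine gene CCL26 8.37-fold, RFPL2 7.51-fold, DEDD2, which stands in the list of heat shock proteins and HSF1 targets, 7.48-fold and MICB, a stress-induced ligand of the NKG2D receptor, 6.92-fold. The folds of PGF, CCL26 and RFPL2 are approximate, since their control levels were under 4.92. The largest falls were those of CYP1B1, a xenobiotic-metabolising cytochrome P450 gene, by 1.47 ± 0.13 on the log2 scale, PDE7B by 1.28, EDN2, which encodes endothelin 2, by 1.26, ZNRF3, a Wnt pathway inhibitor gene, by 1.24, PDE7A by 1.14 and MEIS2 by 1.13. Among 32 immediate early genes, 11 rose and none fell, with 17 rising and 2 falling adjusted over the list alone. EGR1 rose 2.04-fold, FOSL1 1.91-fold and JUNB 1.76-fold, while FOS differed by 0.08 ± 0.15 (adjusted p = 0.826). The immediate early list passed camera with the preset correlation (adjusted p = 3.68e-10) and with an estimated correlation (adjusted p = 0.0235).

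Cell cycle genes fell after heat shock. Of 42 measured, 26 fell and none rose, and 31 fell adjusted over the list alone. Cyclin genes CCNE2 and CCNE1 fell by 0.99 and 0.88 on the log2 scale, RRM2, a subunit of ribonucleotide reductase, by 0.83 and the mitotic kinesin gene KIF2C by 0.74. The list was lower than other genes with the preset correlation (camera adjusted p = 6.29e-13), and the adjusted p = 0.0818 with an estimated correlation did not pass. Matrix protease genes had 4 of 21 higher, extracellular matrix genes 5 of 27 higher and 1 lower, integrin and migration genes 6 of 35 higher and 2 lower, and TGF-beta signalling genes 5 of 29 higher and 4 lower. In a fit without the array that stood apart 1 matrix protease gene was lower. Adjusted over the list alone these lists had 5 higher and 1 lower, 5 and 1, 6 and 2, and 8 and 5, and the lists passed with the preset correlation alone (adjusted p from 0.147 to 0.167 with an estimated correlation). Cytokine genes had 6 of 29 higher and 4 lower, and the list did not pass (camera adjusted p = 0.11). Proteasome subunits had 3 of 27 members lower, also 3 adjusted over the list alone, with a preset-correlation adjusted p of 0.0115 and adjusted p = 0.454 with an estimated correlation. FGF2 rose 2.02-fold, the only 1 of 22 fibroblast growth factor genes to pass, and also the only 1 adjusted over the list alone. FGFR3 fell by 0.37 on the log2 scale.

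In all, 2330 genes differed between heat shocked and control monolayers, 894 higher and 1436 lower, and 104 of them by at least 2-fold (97 higher and 7 lower). The share of higher calls was 38.4% and became 49.6% with cyclic loess scaling (1092 higher and 1110 lower), so the excess of lower genes depended on the scaling. Without control replicate 1, control replicate 2 or heat shock replicate 1 the count was 1450, 1530 and 1438.

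Wounding alone raised immediate early and matrix protease genes. ANGPTL4, which encodes an angiopoietin-like inhibitor of lipoprotein lipase, rose by 3.33 ± 0.18 on the log2 scale (SE, n = 3; 10.1-fold). The transcription factor genes EGR1, FOS and SNAI2 rose 7.94-fold, 4.13-fold and 4.02-fold. MMP10, a stromelysin gene, rose 3.70-fold, the interstitial collagenase gene MMP1 3.48-fold and ITGA2, the α2 integrin subunit of a collagen receptor, 3.24-fold. ARL14, FAM43A and KANK4 rose 3.53-fold, 3.15-fold and 3.14-fold. The folds of SNAI2, MMP10, MMP1, ARL14, FAM43A and KANK4 are approximate, since their control levels were under 4.92, and KCNK5 ended under it. The largest falls were those of EDN2 by 1.45 ± 0.15 on the log2 scale, ID4 by 1.20, the TGF-beta co-receptor gene TGFBR3 by 1.16, the potassium channel gene KCNK5 by 1.09 and INHBB, an inhibin subunit, by 1.05.

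Of 32 immediate early genes, 15 rose after wounding and none fell, with 18 rising and 3 falling adjusted over the list alone (camera adjusted p = 4.88e-21, and adjusted p = 0.00581 with an estimated correlation). JUN rose 2.46-fold and CCN2, a matricellular protein gene, 2.43-fold. Of 21 matrix proteases and plasminogen system genes, 5 rose and 16 did not pass, and 8 rose adjusted over the list alone (adjusted p = 1.52e-09, and 0.0173 with an estimated correlation). SERPINE2 rose by 0.73 and PLAUR, the urokinase receptor, by 0.52, while PLAU differed by 0.28 ± 0.08 (adjusted p = 0.0827). Of 27 extracellular matrix and fibrosis genes, 7 rose, and 8 rose and 1 fell adjusted over the list alone (adjusted p = 5.76e-06, and 0.0216 with an estimated correlation). They included the laminin gene LAMB3 at 1.86-fold, the hyaluronan synthase gene HAS2 at 1.81-fold and COL4A1 at 1.68-fold.

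Other lists passed after wounding with the preset correlation alone. Among 29 TGF-beta signalling genes, 10 rose and 7 fell (12 and 8 adjusted over the list alone), SKIL by 1.03 and TGFBR1 by 0.95 upward, and the adjusted p = 0.0583 with an estimated correlation. Among 35 integrins and migration genes, 5 rose (7 adjusted over the list alone), with RND1 at 1.94-fold and SDC4 at 1.51-fold (adjusted p = 0.0582 with an estimated correlation). Among 29 cytokines and NF-kappaB targets, 4 rose (8 rose and 2 fell adjusted over the list alone), with IL11 at 1.83-fold and TNFAIP3 at 1.79-fold (adjusted p = 0.168 with an estimated correlation). Cell cycle genes had 5 members lower of 42 (10 adjusted over the list alone), with CDC25A at -0.52 and CDC6 at -0.45 (adjusted p = 0.133 with an estimated correlation). FGF2 rose 2.06-fold, 1 of the 22 fibroblast growth factor genes, also 1 adjusted over the list alone, and FGFR3 fell by 0.72 on the log2 scale. Without the array that stood apart, which enters here only through the estimate of spread, 2 of these 22 rose, and 2 rose and 1 fell adjusted over the list alone, an alternative added after the data were seen. Only 2 of the 36 heat shock genes rose, DNAJB2 by 0.32 and HSPB8 by 0.30, also 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.603).

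Wounding changed 648 genes, 411 upward and 237 downward, and 63 of them by at least 2-fold (57 and 6). The count fell to 353, 386 and 425 without control replicates 1, 2 and 3, and to 324 and 306 without wounded replicates 1 and 2.

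Monolayers that were heat shocked and wounded showed both sets of changes against control. HSPA6 rose 87.9-fold, by 6.46 ± 0.26 on the log2 scale (SE, n = 3; limma adjusted p = 1.93e-08), ANGPTL4 16.3-fold, MMP1 15.6-fold and MMP10 14.3-fold. RRAD, a small GTPase gene, rose 11.6-fold, KANK4 11-fold, ARL14 10.7-fold, PGF 10.3-fold, SNAI2 8.68-fold and FAM43A 8.67-fold. The folds of HSPA6, MMP1, MMP10, KANK4, ARL14, PGF, SNAI2 and FAM43A are again approximate, as are the values of FGF1, FGF13 and COL1A1, which were also under 4.92 in control, and of SARM1, which ended under it. EDN2 fell by 2.37 ± 0.15 on the log2 scale, PDE7B by 2.04, the caveolar gene CAVIN2 by 1.96, ZNRF3 by 1.91, CYP1B1 by 1.77, SARM1 by 1.74 and PKDCC by 1.71. FGF1 rose 4.38-fold and FGF2 3.20-fold, and FGF13 rose by 0.30. These were 3 of the 22 fibroblast growth factor genes, and the same number adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.297 with an estimated correlation). When the array that stood apart was left out, FGF13 did not pass (adjusted p = 0.121), so 2 rose, also 2 adjusted over the list alone, and the camera adjusted p was 0.0499.

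**Figure D1:**
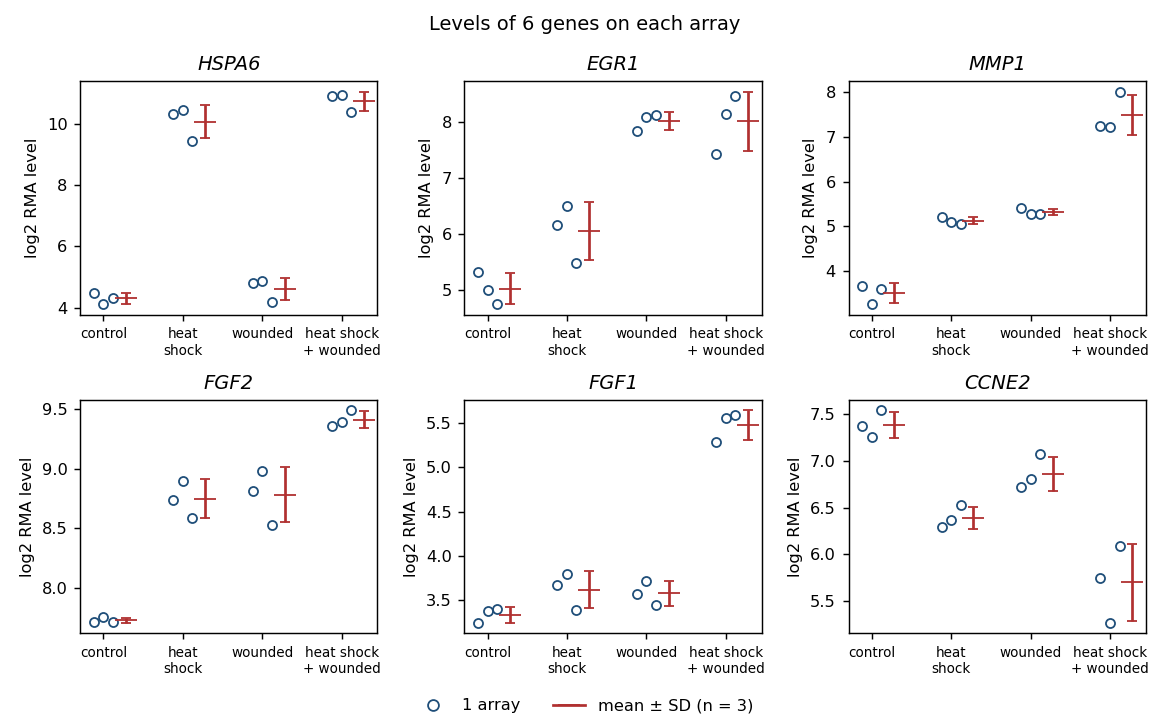
Log2 RMA levels (vertical axis) of HSPA6, EGR1, MMP1, FGF2, FGF1 and CCNE2 in the 4 groups (horizontal axis). Each circle is 1 array and the bar is the group mean with its SD (n = 3). The 3 FGF1 values of the heat shocked and wounded group lie at 5.28 or above, and those of the other 9 arrays at 3.80 or below.

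List counts for both treatments against control were as follows. Of 36 heat shock genes, 30 rose and 1 fell (32 and 1 adjusted over the list alone; camera adjusted p = 1.32e-27, and 0.0293 with an estimated correlation). Of 32 immediate early genes, 21 rose and 2 fell (24 and 2 adjusted over the list alone; adjusted p = 1.23e-13, and 0.0277 with an estimated correlation), with EGR1 at 7.91-fold, JUNB at 3.42-fold and JUN at 3.28-fold. Of 21 matrix protease genes, 11 rose and none fell (11 adjusted over the list alone; adjusted p = 1.31e-06, and 0.0293 with an estimated correlation), with PLAUR at 2.59-fold and PLAU at 1.7-fold. Of 27 extracellular matrix genes, 10 rose and 2 fell (the same numbers adjusted over the list alone; adjusted p = 0.000131, and 0.0293 with an estimated correlation), with LAMB3 at 2.97-fold, COL4A1 at 2.26-fold and COL1A1 at 2.08-fold. Of 42 cell cycle genes, 34 fell and none rose (38 fell adjusted over the list alone; adjusted p = 3.71e-20, and 0.0293 with an estimated correlation), with CCNE2 falling by 1.68 and KIF11 by 0.94 on the log2 scale. Without the array that stood apart, the heat shock, immediate early, matrix protease and extracellular matrix lists still passed with an estimated correlation (adjusted p from 0.0264 to 0.0463), and the cell cycle list had an adjusted p of 0.05. Immediate early genes then had 1 member lower instead of 2 and extracellular matrix genes 0 instead of 2 (1 and 1 adjusted over the list alone). That alternative was added after the data were seen.

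Further lists moved in the combined group with the preset correlation. NRF2 and oxidative stress genes had 9 of 23 members lower and 2 higher (12 and 2 adjusted over the list alone). GCLC, the catalytic subunit of the enzyme that limits glutathione synthesis, fell by 0.73 on the log2 scale, SLC7A11, the cystine transporter, by 0.64 and NFE2L2, the NRF2 gene itself, by 0.66 (camera adjusted p = 0.00254, and adjusted p = 0.289 with an estimated correlation). With the array that stood apart left out 7 were lower, also 7 adjusted over the list alone. Of 29 TGF-beta signalling genes, 13 rose and 6 fell (15 and 6 adjusted over the list alone; adjusted p = 0.0858 with an estimated correlation), with BMP2 rising 2.74-fold and BMP4 falling by 1.42. Of 35 integrin and migration genes, 12 rose and 2 fell (12 and 3 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation), with ITGA2 at 5.42-fold. Of 29 cytokine genes, 9 rose and 2 fell (11 and 3 adjusted over the list alone; adjusted p = 0.299 with an estimated correlation), with IL11 at 4.81-fold and CXCL8 at 2.39-fold.

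**Figure D2:**
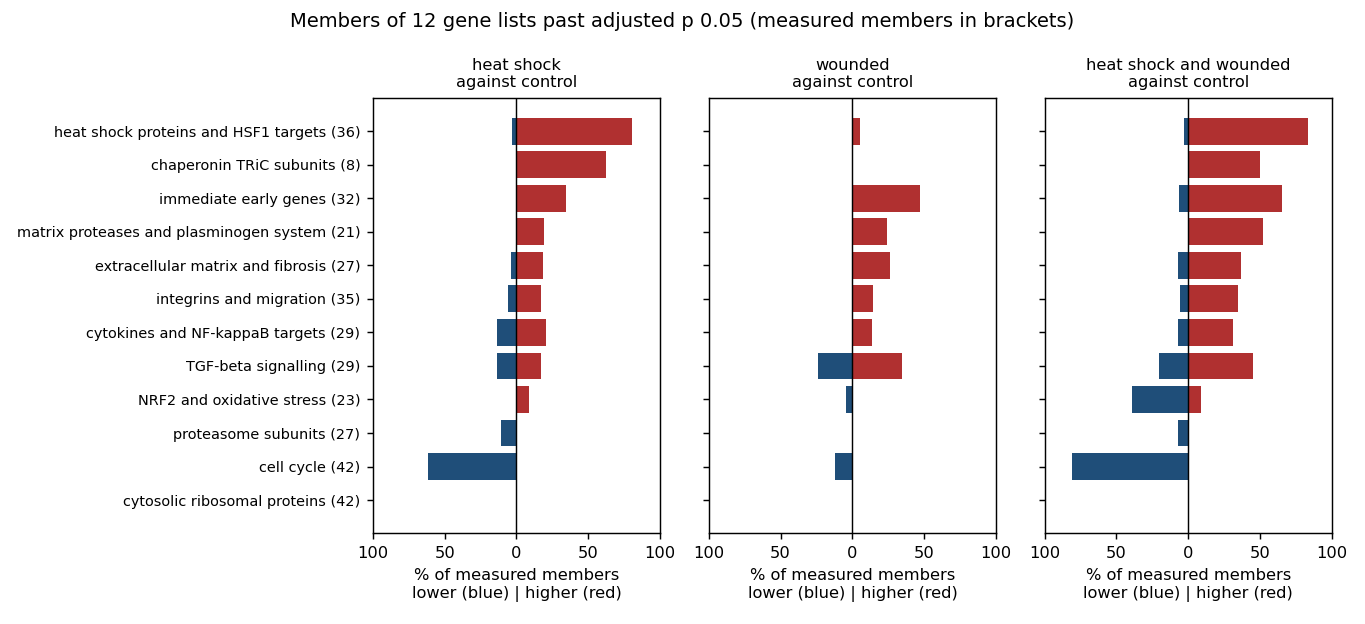
Share of the measured members of 12 gene lists (rows, number measured in brackets) that passed an adjusted p of 0.05 in each treated group against control. Bars to the right of 0 are members that were higher and bars to the left members that were lower, in percent. Heat shock genes rose in the 2 heat shocked groups (29 and 30 of 36) and cell cycle genes fell there (26 and 34 of 42), while 42 cytosolic ribosomal protein genes had no member past the threshold.

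The combined treatment changed 4180 genes against control, 1571 upward and 2609 downward, and 292 by at least 2-fold (234 and 58). The share of higher calls was 37.6% and became 50.1% with cyclic loess scaling (1935 higher and 1928 lower). Of the 4180 genes, 1979 also passed in the same direction after heat shock alone, 555 after wounding alone, and 313 in both, while 1954 passed in neither in any direction. These are overlaps of comparisons that share the control arrays. The 1954 genes are not shown to respond only to both treatments, since single effects under the threshold can add up. Only 1 gene passed the interaction.

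Heat shock before wounding was compared with wounding alone. HSPA6 was 70.9-fold higher, PGF 13.6-fold, SERPINH1 8.25-fold, HSPA4L 7.31-fold, CCL26 7.25-fold and MICB 7.19-fold. MMP1 was 4.48-fold higher, MMP10 3.86-fold, FGF1 3.72-fold, ANKRD1 3.17-fold, IL11 2.62-fold, SNAI2 2.16-fold and SNAI1, which encodes the transcription factor Snail, 2.08-fold. The folds of HSPA6, PGF, CCL26 and FGF1 are approximate, since their wounded levels were under 4.92. PDE7B fell by 1.40 ± 0.13 on the log2 scale (SE, n = 3), ZNRF3 by 1.30, CYP1B1 by 1.25, DNA2, a DNA replication nuclease gene, by 1.20, CCNE2 by 1.16 and the Wnt feedback gene AXIN2 by 1.05. FOS fell by 0.50 and NR4A2 by 0.71, and EGR1 differed by -0.01 ± 0.27 (adjusted p = 0.991).

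Of 36 heat shock genes, 30 were higher and 1 lower in this comparison (32 and 1 adjusted over the list alone), and of 42 cell cycle genes 30 were lower (30 lower and 1 higher adjusted over the list alone). Of 32 immediate early genes 10 were higher and 2 lower (14 and 2), and of 21 matrix protease genes 7 were higher and 1 lower (8 and 1), each pair in brackets adjusted over the list alone. Without the array that stood apart, 6 immediate early genes were higher and 1 lower (8 and 3), with a mean of 0.13 against 0.15, and no matrix protease gene was lower (1 adjusted over the list alone). Of the 33 lists, 8 were higher and 2 lower than other genes with the preset correlation, and none passed with an estimated correlation, where the heat shock list had an adjusted p of 0.0686 and the cell cycle list an adjusted p of 0.0693. In all, 2704 genes differed, 1144 higher and 1560 lower, and 100 by at least 2-fold. The share of higher calls was 42.3% and became 53.1% with cyclic loess scaling (1320 higher and 1168 lower), and the count was 1649 without wounded replicate 1 and 1663 when only the arrays of both groups entered the fit.

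Wounding after heat shock was compared with heat shock alone. ANGPTL4 was 6.90-fold higher, by 2.79 ± 0.18 on the log2 scale (SE, n = 3), MMP1 5.12-fold, SNAI2 4.8-fold, MMP10 4.77-fold and FAM43A 4.57-fold. EGR1 was 3.88-fold higher, KANK4 3.72-fold, GAL, which encodes the neuropeptide galanin, 3.68-fold, FGF1 3.62-fold and F3, the tissue factor gene, 3.21-fold. The values of SNAI2, KANK4, FGF1 and ITGB8 are approximate, since their levels after heat shock were under 4.92. CAVIN2 fell by 1.39 ± 0.14 on the log2 scale, EDN2 by 1.11, the ETS factor gene EHF by 1.03, TOB1 by 0.98, AJUBA by 0.95 and the integrin gene ITGB8 by 0.91. Of 32 immediate early genes, 13 were higher and 3 lower (15 and 3 adjusted over the list alone; camera adjusted p = 4.43e-08, and 0.0455 with an estimated correlation). A fit without the array that stood apart had 12 higher and 0 lower, with 15 and 3 adjusted over the list alone. Of 21 matrix protease genes 7 were higher (9 adjusted over the list alone) and of 27 extracellular matrix genes 9 were higher (11 higher and 1 lower adjusted over the list alone), each with an adjusted p of 0.0414 with an estimated correlation. None of the 36 heat shock genes passed, over all genes or adjusted over the list alone, and HSPA1B differed by 0.03 ± 0.20. NRF2 genes had 7 of 23 members lower (8 adjusted over the list alone), with OSGIN1 at -0.89 and GCLC at -0.64. The list had a camera adjusted p of 2.72e-07, and adjusted p = 0.0931 with an estimated correlation. Of 42 cell cycle genes 7 were lower (20 adjusted over the list alone; adjusted p = 0.0899 with an estimated correlation), and without the array that stood apart none passed over all genes and 14 did adjusted over the list alone, with a median of -0.19 in both fits. Without it 4 extracellular matrix genes were higher instead of 9 (10 instead of 11 adjusted over the list alone), with a mean of 0.21 against 0.23. That alternative was added after the data were seen.

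Monolayers given both treatments differed from those only heat shocked in 779 genes, 492 higher and 287 lower, and 65 by at least 2-fold. The collection time of monolayers that were only heat shocked is not given, so time may account for part of these differences. The count was 512 without heat shock replicate 2, 498 without heat shock and wounded replicate 2, and 300 when only the arrays of both groups entered the fit.

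FGF1 is named in the series title, and it rose where both treatments were given. Its log2 level was 3.34 ± 0.09 in control, 3.62 ± 0.21 after heat shock, 3.58 ± 0.14 after wounding and 5.47 ± 0.17 after both (SD, n = 3). The combined group exceeded control by 2.13 ± 0.12 (SE; limma adjusted p = 1.6e-07), wounding alone by 1.89 ± 0.12 (adjusted p = 1.42e-06) and heat shock alone by 1.85 ± 0.12 (adjusted p = 1.51e-05), and all 3 of its arrays lay above the other 9 arrays. Heat shock alone gave 0.28 ± 0.12 (adjusted p = 0.152) and wounding alone 0.24 ± 0.12 (adjusted p = 0.42). The heat shock value passed with array weights and without heat shock replicate 3 (0.39, limma adjusted p = 0.0414). It ranged from 0.19 to 0.39 with 1 array left out. The interaction, the part of the combined effect beyond the sum of the single effects, was 1.62 ± 0.16 (adjusted p = 0.00623), and FGF1 was the only 1 of 18132 genes to pass that test (1302 had an unadjusted p under 0.05, and 2 genes passed without control replicate 3). The probe set read for FGF1 had the highest mean of the FGF1 probe sets only with the combined arrays included. FGF2 differed in the other direction without passing, with an interaction of -0.38 ± 0.15 (adjusted p = 0.635).

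The other 3 probe sets of FGF1 were also higher in the combined group than in control, by 1.02, 0.72 and 1.20, and their interactions of 0.70 ± 0.24, 0.32 ± 0.17 and 0.76 ± 0.20 did not pass (adjusted p from 0.581 to 0.745 over all probe sets). FGF1 was dim, with its control level at the 19.2 percentile of all genes, but probe sets differ in affinity and background was not measured, so whether the single-treatment levels lay at background is not known. The interaction call was lost when the probe sets of a gene were averaged (0.85, adjusted p = 0.137) and when both S2 arrays of a group were averaged (1.75, adjusted p = 0.0675). Genes with the next smallest p for the interaction were SOX18 (0.73 ± 0.12, adjusted p = 0.281), VASN (0.96 ± 0.16, adjusted p = 0.281), ITPRIPL1 (0.62 ± 0.11, adjusted p = 0.315) and TAMALIN (0.63 ± 0.11, adjusted p = 0.315). Immediate early genes and NRF2 genes were lower as lists in the interaction with the preset correlation (camera adjusted p = 0.00047 and 5.58e-05), with adjusted p = 0.441 for both with an estimated correlation. EGR1 had an interaction of -1.03 ± 0.38 (adjusted p = 0.625), FOS -0.58 ± 0.22 (adjusted p = 0.625) and MMP1 0.56 ± 0.25 (adjusted p = 0.683).

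Most genes that passed after 1 treatment alone had the same sign when the other treatment was present. Across all genes, which are not independent replicates, the wounding effect in heat shocked monolayers correlated with that in unheated ones at Pearson's r = 0.59 (Spearman's rho 0.33). Of the 648 genes that wounding alone changed, 627 (96.8%) had the same sign after heat shock, with r = 0.91 and a slope of 0.84, and 368 passed in both in the same direction. The heat shock effect with and without wounding correlated at r = 0.77 (rho 0.58). Of the 2330 genes that heat shock alone changed, 2264 (97.2%) had the same sign in wounded monolayers, with r = 0.95 and a slope of 0.89, and 1589 passed in both. These effects share no arrays within a pair. The r and slope over called genes used genes chosen by their effect without the other treatment. Such a choice raises r and pulls a slope under 1. The slopes were fitted through the origin, and they do not show damping of either effect.

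**Figure D3:**
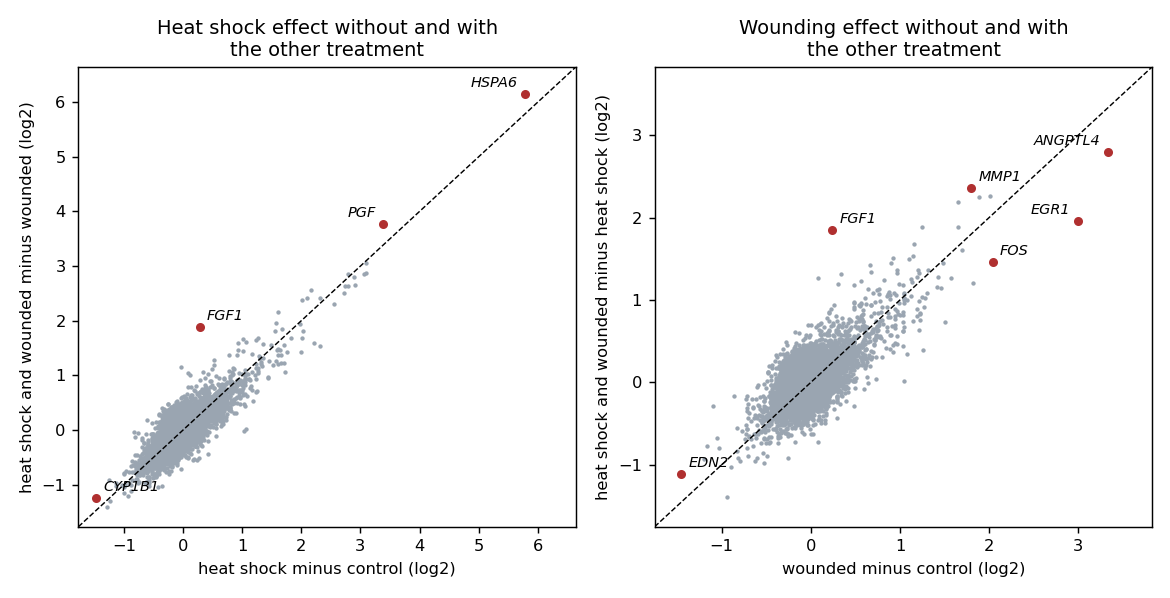
Effect of heat shock (left) and of wounding (right) on each of 18132 genes, in log2, without the other treatment (horizontal axis) and with it (vertical axis). Each grey point is a gene, named genes are red and the dashed line marks equal effects. FGF1 lies at 0.28 and 1.89 for heat shock and at 0.24 and 1.85 for wounding, away from the line.

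Heat shock and wounding were also compared with each other through their shared control. The effects correlated at 0.41, against 0.50 simulated for unchanged groups with shared controls, and the covariance was 0.0176 against 0.00541 simulated, a difference of 0.0122. A total of 199 genes rose in both, against 20.3 for independent lists, and 117 fell in both, against 18.8. With the 3 controls split between both effects, 1 for one and 2 for the other, so that no array was shared, the correlation was 0.24 to 0.28 over the 6 splits, a check added after the data were seen. Genes higher in both included ANGPTL4, EGR1, MMP1, MMP10, SNAI2, ITGA2, FGF2, IL11 and RND1, and EDN2 and TGFBR3 were lower in both.

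The descriptions carry the set labels S2a, S2b and S3a, whose meaning is not given, and each group had 2 arrays in set S2 and 1 in set S3. Within S2 alone, 1837, 485 and 3962 genes passed for heat shock, wounding and both against control, 2185 for both against wounding and 386 for both against heat shock. Of the genes called within S2, 1722 of 1837, 471 of 485, 3608 of 3962, 2007 of 2185 and 356 of 386 had the same sign in the single S3 arrays, which did not enter those calls. Within S2 the FGF1 interaction was 1.35 (adjusted p = 0.299) and in S3, without replicates, 2.16. The fit within S2 was added after the data were seen.

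The remaining lists are given here for heat shock, wounding and both. Endoplasmic reticulum stress genes had 6, 0 and 7 of 25 higher and 1, 0 and 1 lower, with TRIB3 at 0.79 after heat shock and SESN2 at 0.88 after both, and adjusted p = 0.166 after heat shock and 0.289 after both with an estimated correlation. Apoptosis genes had 7, 5 and 8 of 21 higher and 0, 1 and 1 lower, led by MCL1, an anti-apoptotic BCL2 family gene, at 0.59, 0.78 and 1.33, with adjusted p = 0.0769, 0.0778 and 0.0622 with an estimated correlation. The p53 targets had 4, 4 and 9 of 22 higher and 0, 0 and 3 lower, with BTG1 at 0.56, 0.68 and 0.85 (adjusted p = 0.447, 0.269 and 0.384 with an estimated correlation). YAP and SRF targets had 4, 3 and 7 of 20 higher and 1, 1 and 5 lower, with F3 at 1.61 after both (adjusted p = 0.099, 0.927 and 0.58 with an estimated correlation). Hypoxia and glycolysis genes had 3, 4 and 7 of 28 higher and 2, 0 and 3 lower, with PFKFB4 at 1.09, 0.92 and 1.55 (adjusted p = 0.726, 0.0671 and 0.534 with an estimated correlation). Metallothionein genes and their regulators had 1, 1 and 3 of 12 higher, with MT2A at 0.60 after both (adjusted p = 0.0858 after both with an estimated correlation). Epithelial mesenchymal transition genes had 2, 1 and 5 of 22 higher and 0, 0 and 4 lower, EGF receptor family genes 1, 2 and 4 of 15 higher and 2, 0 and 3 lower, with EGFR at 0.57, 0.53 and 0.81, and FGF receptors and feedback genes 0, 1 and 2 of 19 higher and 3, 1 and 3 lower, none of these 3 lists passing camera. Leaving out the array that stood apart, YAP and SRF targets had 3 lower after both instead of 5, epithelial mesenchymal transition genes 2 lower instead of 4, EGF receptor family genes 2 higher instead of 4 and apoptosis genes 0 lower instead of 1. After wounding, epithelial mesenchymal transition genes then had 2 higher instead of 1, FGF receptors and feedback genes 2 higher instead of 1 and p53 targets 1 lower instead of 0.

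Lists of cell types and basal functions follow in the same order. Of 15 alveolar type II markers 0, 0 and 3 were higher and 1, 0 and 2 lower, of 10 alveolar type I markers 2, 0 and 1 were lower, and of 12 fibroblast markers 1, 0 and 1 were higher and 1, 0 and 0 lower, COL1A1 at 0.78 and 1.05. Endothelial markers had 0, 0 and 2 of 10 higher, ESAM at 0.49 and TIE1 at 0.28 after both, and none of 13 leukocyte markers passed in any comparison. Cholesterol synthesis genes had 3, 0 and 3 of 18 higher and 4, 0 and 4 lower (3 higher and 7 lower after heat shock adjusted over the list alone), with HMGCS1 at 0.70 after heat shock. Without the array that stood apart, cholesterol synthesis genes had 1 member lower after both instead of 4 (2 instead of 8 adjusted over the list alone), endothelial markers 1 higher instead of 2, alveolar type II markers 1 lower instead of 2 and fibroblast markers 1 lower instead of 0. In the same fit, histone genes had 4 lower after heat shock instead of 1 (also 4 adjusted over the list alone) and 1 lower after both instead of 2, and oxidative phosphorylation genes had a camera adjusted p of 0.0698 after heat shock. After both, oxidative phosphorylation genes 0 instead of 2, and interferon-induced genes 1 lower and 2 higher instead of 2 and 1. Interferon-induced genes had 2, 0 and 2 of 24 lower and 0, 0 and 1 higher, replication-dependent histone genes 1, 0 and 2 of 17 lower, and oxidative phosphorylation genes 1, 0 and 2 of 30 lower (camera adjusted p = 0.049 after heat shock, and adjusted p = 0.602 with an estimated correlation). None of 42 cytosolic ribosomal protein genes passed in any comparison. Of 11 housekeeping genes 2, 0 and 1 were lower, with TFRC at -0.35 after heat shock and -0.34 after both. GAPDH differed by -0.04 ± 0.05, -0.02 ± 0.05 and -0.03 ± 0.05 and ACTB by 0.10 ± 0.10, 0.04 ± 0.10 and 0.02 ± 0.10, none past the threshold.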

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

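The tests of a single array, of the other FGF1 probe sets and of dim genes chosen on 1 array were chosen after the result was seen. FGF1 had effects of heat shock that differed between unwounded and wounded monolayers, with an interaction of 1.62 on the log2 scale. That value came from a probe set whose choice included the combined group. The lowest interaction after leaving out 1 array was 1.5 (highest 1.71), which argues against 1 array as its source. The other 3 FGF1 probe sets had a mean interaction of 0.59 ± 0.15 (SE). That argues against off-target signal of the chosen probe set as the whole source, provided that the probe sets share no probes, which was not checked. The part of 1.62 beyond 0.59 may still be particular to the chosen probe set. Background stays open: among genes at least 2-fold higher with both treatments, 25 with a control level under 4 had a median interaction above that of 208 brighter genes by 0.26 (two-sided permutation p = 0.00244), although the 95% bootstrap interval of -0.18 to 0.42 held 0, and the difference was 0.04 to 0.25 with genes chosen on 1 control and 1 combined array and measured on the other arrays. Among those 25 dim genes the highest interaction was 1.19, under the 1.62 of FGF1. With an additive background, a gene-specific control signal of 0.13 within a linear level of 10.2 would make both effects multiply without interaction, and single-treatment rises would then be 18-fold and 15-fold. A joint action of both treatments on FGF1 is a hypothesis that these arrays do not separate from background. An assay of FGF1 with a measured background in the single treatments would address background alone. Such an assay would leave open the collection time of monolayers that were only heat shocked, which the labels do not give.

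Only 3 of 100 random regroupings of the 12 arrays into 4 groups of 3, the real one included, called as many genes for the interaction as the real count of 1, but these regroupings mix the treatment effects into the spread and so do not decide whether chance gave that count. The highest count of another regrouping was 31, several times the real count, which points to a structure of the samples. The treatments are such a structure, and that regrouping put 5 of the 6 heat shocked arrays on 1 side of its interaction contrast. With the single effects kept and the residuals of a model without interaction assigned to the arrays at random, a test chosen after the result was seen, 4 of 100 assignments, the real one included, called as many genes, with a highest other count of 1. That share is under 0.05 only if the arrays can be exchanged, while 12 of 18 pairs of same-numbered arrays correlated above 0.1 in deviations, and the count was 0 with S2 arrays averaged and within S2, so chance stays open.

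Signals also appeared in the 4305 probe sets with several gene symbols or none listed, outside the tests by gene. Adjusted over all probe sets, 348 of them passed for heat shock against control, 76 for wounding, 661 for both, 412 for both against wounding and 94 for both against heat shock. For the interaction 1 passed, an unlisted probe set with -1.26 ± 0.15 (adjusted p = 0.0314) and group means of 10.38, 11.32, 11.50 and 11.17 for control, heat shock, wounding and both.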

How the results depend on the processing

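Counts of changed genes are given for heat shock, wounding and both against control, then for both against wounding and both against heat shock. The fits on all arrays gave 2330, 648, 4180, 2704 and 779. Testing all probe sets separately gave 4347, 1113, 8816, 5416 and 1352, where a gene can count more than 1 time. Averaging both S2 arrays of each group gave 919, 224, 2475, 1104 and 333. A change of at least 2-fold added to the adjusted p gave 104, 63, 292, 100 and 65, a 1.5-fold change 471, 232, 1088, 525 and 254, and an adjusted p under 0.01 gave 1114, 303, 2533, 1279 and 371. Array weights gave 3871 for heat shock and 1436 for wounding. Fits with the compared groups alone gave 1663 against wounding and 300 against heat shock. The fit within S2, added after the data were seen, gave 386 against heat shock. The cause of these shifts was not tested.

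With 1 array left out, the counts ranged from 1438 to 2594, 306 to 722, 3088 to 4400, 1649 to 2936 and 498 to 790. Lists passing camera ranged from 12 to 14, 10 to 12, 15 to 16, 8 to 11, 6 to 10, and from 2 to 5 for the interaction. With an estimated correlation 3, 3, 5, 0 and 3 lists passed, and 0 for the interaction.

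The interaction called 1 gene on all arrays. It called 0 with the lowest 30% or 50% of genes left out, where FGF1 was not tested, and 0 with the mean of all probe sets of a gene, with S2 arrays averaged and within S2. It called 2 with all probe sets, 2 with a trended robust prior, and 1 to 2 with 1 array left out. The FGF1 interaction was 0.85 (adjusted p = 0.137) with the mean of probe sets, 1.75 (adjusted p = 0.0675) with S2 arrays averaged and 1.35 (adjusted p = 0.299) within S2. FGF1 after heat shock was 0.35 (adjusted p = 0.0191) with array weights and 0.39 (adjusted p = 0.0414) without heat shock replicate 3, within a range of 0.19 to 0.39.

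The wounding effects with and without heat shock correlated at 0.7 and 0.77 with the lowest 30% and 50% of genes left out and at 0.5 with all probe sets, and at 0.52 to 0.60 with 1 array left out. The heat shock effects correlated at 0.84, 0.89 and 0.72, and at 0.73 to 0.77.

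Arrays of the same number were not taken as pairs. In deviations from group means, 12 of 18 pairs of same-numbered arrays correlated above 0.1 (range -0.14 to 0.42). With the number as a fixed block the counts were 2370, 639, 4230, 2728 and 817, and 1 for the interaction, and the random block had a correlation of 0.009.

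For 190 gene values named in the text, 4950 of 5083 values under the alternatives kept direction and side of the threshold, 110 no longer passed, 7 newly passed and 16 changed sign. Those 16 belonged to differences near 0 that had not passed. HSPA8 after heat shock was -0.15 with the mean of probe sets. FOS after heat shock was -0.02 with S2 arrays averaged and ranged from -0.08 to 0.24 with 1 array left out. EGR1 with both treatments against wounding was 0.04 with quantile normalization again, 0.05 with cyclic loess, 0.24 with the mean of probe sets and 0.08 with S2 arrays averaged, and ranged from -0.23 to 0.29. ACTB ranged from -0.01 to 0.16 after heat shock, -0.01 to 0.08 after wounding and -0.03 to 0.08 after both, and HSPA1B with both treatments against heat shock from -0.02 to 0.09. Background was not measured here, so the level at which signal is lost is not given.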

Other observations

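Genes called in both single treatments were followed in the combined group. Of 199 genes higher after heat shock and after wounding, 196 had a further positive estimate for wounding after heat shock, and 135 of them passed. Of 117 lower in both, 108 had a further negative estimate. This was not particular to genes called in both, since 627 of all 648 genes called after wounding kept their sign after heat shock and 266 of the 411 higher ones passed again. IL11, a cytokine of the IL-6 family, rose 2.24-fold and 1.83-fold with the single treatments and 4.81-fold with both.

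The tests of shared controls were chosen after the shared calls were seen, and the first used arrays that enter with opposite sign. Heat shock minus control and both minus heat shock share the heat shock arrays, so shared noise pulls their correlation below 0, to -0.50 in simulated groups without effect. The observed correlation across genes was 0.14, and 0.14 likewise for wounding minus control with both minus wounding, with a covariance of 0.00638 against -0.00539 simulated. With separate controls for heat shock and wounding, the lowest correlation over 6 splits of the controls was 0.24. Shared control arrays as the whole source of the common changes are thus argued against. Handling steps common to both treatments stay open and untested, and a common response to both injuries is a hypothesis that a sham-handled group would separate from handling.

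Replicate 2 of the heat shock and wounded group stood apart. The combined effect explained 0.1% of the variance of its deviation across genes, which decides nothing because both were taken from the same other 2 arrays with opposite sign. The sum of the single effects, which shares no array with the deviation and was tested after that result was seen, explained 1.3% (r = 0.11, slope 0.07), which argues against a stronger response as the source of most of the deviation. A slightly stronger response stays open, since the slope was positive and the array lay at 29 on the first principal component against 20.6 and 17. It also departed on the third component (9.8% of the variance), at -18.9 against 5.3 and 10.9 in its group and -9.3 to 7.5 in the other groups. The level of a gene explained 6.3% (r = -0.25), between the bounds set for and against a compressed signal range, so that explanation and others cannot be told apart with 1 array. Its deviation had a median of 0.10 in the 25% of genes with the lowest level and -0.02 in the 25% with the highest.

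The 3 against 3 comparisons have 10 splits of 6 arrays, too few for a share under 0.05. In each, 1 split, the real one, gave the highest count. The real counts were 2330, 648, 4180, 2704 and 779, and the highest of other splits were 1, 0, 0, 0 and 0. Every other split mixes the compared groups and puts the treatment effects into the spread, so these low counts do not decide about chance.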
